A study of Mus musculus with 12 samples.

How the data were processed

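Kidneys of male BALB/c mice aged 8 weeks, an inbred laboratory strain, were profiled by RNA sequencing in 4 treatment groups of 3 mice each. Per the labels' protocols, total RNA was prepared with a silica column kit and treated with DNase, and libraries were made with an Illumina TruSeq RNA kit, which keeps no strand information in its basic form. The submitters' processing notes list Trimmomatic, TopHat, Cufflinks, HTSeq, bedtools and DESeq and the mouse build mm10, with no version, role or order. How reads were trimmed, aligned and counted in detail is not given in the sources used here.

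The authors deposited a table of whole-number read counts per Ensembl gene, with 1 column per library and no pooling of replicates. They also deposited a table of normalised signal, in which each column equals the counts divided by 1 size factor. In all 12 columns this factor equalled the median-of-ratios factor recomputed from the counts within a tolerance of 0.0001. All results come from the counts, and the normalised table was used for an alternative only. The count table held 28991 gene identifiers, of which 27955 were matched by identifier to a symbol and a position in GENCODE M21 (build GRCm38, the same assembly as mm10). The remaining 1036 have no symbol here. No line of the table was a total or an unassigned class.

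Library totals ran from 29505929 to 62237514 counts, and cisplatin-treated mice had the lower ones. Precision is therefore limited by the 3 mice per group rather than by counting for well-expressed genes. Pairs of replicates were compared by a chi-square test over genes with at least 10 counts. Chi-square per degree of freedom ran from 4.4 to 26.3 (expected near 1 for a library deposited more than once), so every library was counted as a separate sample. The labels call the replicates biological, and each was taken as a separate mouse.

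Genes passing filterByExpr of edgeR 4.0.16 (20370 genes) were tested in R 4.3.3 with the edgeR quasi-likelihood test after TMM scaling. All 12 libraries were fitted in 1 model with a mean per group, so that all groups shared 1 estimate of the spread (biological coefficient of variation 0.092, 8 residual degrees of freedom). Every adjusted p of a gene is the Benjamini-Hochberg value of this 2-sided test unless another tool is named, and a gene was called at an adjusted p below 0.05. Log2 fold changes are given with their standard error (SE), and expression levels as CPM, counts scaled to the TMM-adjusted library total, mean ± SD over 3 mice. The comparisons were cisplatin with saline, dichloroacetate with saline, the combination with cisplatin, the combination with dichloroacetate, the combination with saline, and the interaction. The interaction is the log2 response to cisplatin in mice given dichloroacetate minus that in mice without it.

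A planned summary measured whether the response to cisplatin was smaller with dichloroacetate. It took genes called for the mean cisplatin effect over both pretreatments, a contrast that favours neither arm, and signed each gene's interaction on the log2 CPM scale (prior count 2) by the direction of that mean effect. The median of these values was tested by exact 2-sided permutation of the dichloroacetate label within treated and within untreated mice, which gives 400 arrangements.

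Before the data were examined, 35 gene lists with 896 entries were fixed, of which 14 entries were not matched to the table. They covered p53 targets, tubular injury, proximal tubule transport, fatty acid oxidation and PPARA targets, glycolysis, gluconeogenesis, the pyruvate dehydrogenase complex and its regulators, the citric acid cycle, the nuclear-encoded respiratory chain, NRF2 targets, glutathione transferases and glutathione metabolism, inflammatory cytokines and NF-kB response, endoplasmic reticulum and integrated stress, proliferation, apoptosis and regulated necrosis, the circadian clock, cholesterol synthesis, fatty acid synthesis, heat shock and metal response, early response genes, male-biased kidney genes, and cisplatin uptake, export and bioactivation. Further lists held cytosolic ribosomal proteins, mitochondrially encoded genes, and markers of loop of Henle and distal tubule, collecting duct, podocytes, endothelium, macrophages, neutrophils, lymphocytes, fibroblasts and smooth muscle, adipocytes, erythroid cells and adrenal gland. The 34 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. The adrenal list had fewer tested members and was not tested. Beside each camera result stands the value obtained with a correlation estimated per list, and fry was run as a further alternative. Fry asks whether a list's genes move 1 way on balance and does not compare them with other genes.

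Genes named in the text follow a rule fixed in advance. For cisplatin with saline, dichloroacetate with saline and the combination with cisplatin, it takes the 8 largest rises and the 8 largest falls among called genes with at least 5 CPM in the higher group and no overlap between the groups' libraries, leaving out unnamed gene models. It adds up to 4 members of each list with the smallest adjusted p, the 10 interaction genes with the smallest adjusted p, and in every comparison Havcr1, Lcn2, Cdkn1a, Pdk1, Pdk2, Pdk3, Pdk4, Cyp4a14, Cpt1a, Slc34a1 and Slc22a2, with 1 more gene that is not reported here. The rule gave 234 genes, and the text names 131 of them. Which list members to name was decided after their values were seen. A gene named under the rule in a comparison may be given again for another.

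The kit was taken to be the basic one without strand marking, and the strand setting of the counting is not given in the sources used here. Without strand, reads from genes that overlap on opposite strands cannot be told apart, and their values are uncertain. Of the 131 named genes, 42 overlap an annotated gene on the other strand, and 20 of these a protein-coding one. They are Acsm3 and Eri2, which overlap each other, Slc34a1 (Pfn3), Slc7a7 (Oxa1l), Fosl1 (Ccdc85b), Junb (Prdx2), Cxcl10 (Art3), Alas2 (Apex2), Pdha1 (Map3k15), Pcx (Lrfn4), Gstz1 (Pomt2), Csf1r (Hmgxb3), Acaca (Gm11437), Kcnh1 (Hhat) and, at their ends, Atp5a1, Ccnd1, Cyp51, Dennd1a, Ndufs1 and Slc25a21. The other 22 overlap only antisense or other noncoding genes, pseudogenes or provisional gene models: Abcb1b, Acsl1, Atf3, Cdkn1a, Cubn, Dpys, Egf, Fhit, Gna14, Herpud1, Ldlrad3, Malat1, Nav2, Nudt19, Pdk2, Pzp, Slc13a2, Slc27a2, Slco1a6, Snx29, Thrb and Txnrd1. Dennd1a, Gstz1 and Ndufs1 overlap noncoding genes inside as well. Values of Acot1 and Acot2, of the Gst, Cyp4a, Slco1a and Slc22a families and of the alpha-globin genes are uncertain because near-identical copies can share reads.

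The pipeline was tested on simulated counts with 200 changed genes. For cisplatin with saline, 60.6%, 77.3% and 95.5% of genes changed by 1.5-, 2- and 4-fold were recovered, with 8 false calls among 20070 genes. For dichloroacetate with saline the shares were 58.5%, 83.1% and 95.5%, with 8 false calls among 20053 genes. For the interaction they were 35.8%, 62.7% and 78.8%, with 7 false calls among 20089 genes. In a simulation with a smaller response in the combination, the summary median was -0.376 as measured and -0.376 as simulated (exact permutation p = 0.005).

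Alternatives were DESeq2 1.42.0, limma-voom, limma on log2 of the authors' normalised values plus 1, RLE scaling, no filter on low counts, a filter of 1 CPM in at least 3 libraries, the replicate number as a block, an added absolute log2 fold change of at least 1, fits on the 6 libraries compared, and leaving out each library in turn. An alternative chosen after seeing the data removed mitochondrially encoded genes before scaling. Other splits of the mice were refitted, all 10 for each comparison of 2 groups and 80 drawn arrangements for the interaction. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.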

Results

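Cisplatin is a platinum chemotherapy drug whose dose is limited by injury to the kidney tubule, and dichloroacetate inhibits the pyruvate dehydrogenase kinases, which switch off the pyruvate dehydrogenase complex. The study set out to test whether dichloroacetate protects the kidney from cisplatin. Whole-kidney RNA was sequenced from 4 groups of 3 male BALB/c mice. The groups received saline, dichloroacetate at 250 mg per kg daily for 6 days, a single cisplatin injection of 20 mg per kg after 5 days of saline, or the same injection after 5 days of dichloroacetate. Kidneys from injected mice were taken 24 h after cisplatin. Library totals were 38236592 to 55832441 counts in saline, 41525403 to 62237514 in dichloroacetate, 29614283 to 35925471 in cisplatin and 29505929 to 35082408 in the combination. The leading principal component held 68.9% of the variance and separated the 6 cisplatin-injected mice from the 6 others, and the next held 6.9%. On the leading component the combination mice scored 27 to 32.5, between the cisplatin mice at 61.5 to 75.9 and the mice without cisplatin at -51.7 to -48.2.

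**Figure D1:**
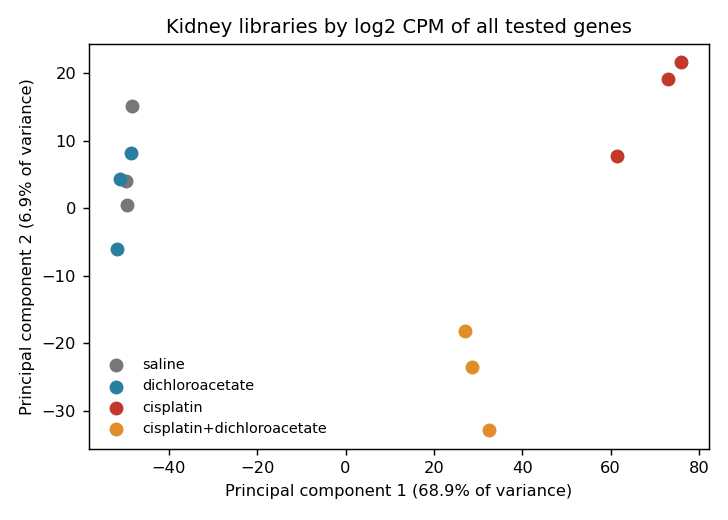
Principal components 1 and 2 of log2 CPM over all tested genes, with 1 point per mouse coloured by treatment group. Component 1 holds 68.9% of the variance and component 2 holds 6.9%, and cisplatin-injected mice lie apart from the other mice along component 1.

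Cisplatin alone was compared with saline to describe the injury response of the kidney. Krt20, an intermediate filament keratin of epithelial cells, had the largest rise, from 0.121 ± 0.0477 to 43.8 ± 3.62 CPM (SD, n = 3), a log2 fold change of 8.46 (SE 0.30, adjusted p = 1.1e-10). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 3.74 ± 0.852 to 377 ± 39.9 CPM, a log2 fold change of 6.65 (SE 0.21, adjusted p = 4.5e-11). The injury marker Havcr1, which encodes KIM-1, rose from 34.3 ± 2.37 to 153 ± 9.51 CPM, a log2 fold change of 2.16 (SE 0.12, adjusted p = 3.5e-09). Slc34a1, the main phosphate transporter of the proximal tubule brush border, fell from 3724 ± 216 to 848 ± 60.5 CPM, a log2 fold change of -2.13 (SE 0.07, adjusted p = 5.8e-11). In build mm10 these genes (identifiers ENSMUSG00000035775, ENSMUSG00000023067, ENSMUSG00000040405 and ENSMUSG00000021490) lie on chromosome 11, 99428403 to 99438150, on chromosome 17, 29090976 to 29100727, on chromosome 11, 46735080 to 46779578 and on chromosome 13, 55398187 to 55415592. Of 20370 genes, 6048 rose and 6196 fell, which is 60.1% of those tested, and 3208 of these changed by at least 1 log2 unit. Camera called 20 of 34 gene lists, 8 up and 12 down, against 1 with an estimated correlation (7 at an unadjusted p below 0.05) and 27 with fry. Other splits of the same 6 mice gave up to 23 camera calls.

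Other large rises were those of Saa4, a serum amyloid A protein, at 6.27 (SE 0.19), Serpina7, thyroxine-binding globulin, at 6.16 (SE 0.20), the glutathione transferase Gstp3 at 5.88 (SE 0.31), the p53-induced receptor Eda2r at 5.72 (SE 0.14), the spindle protein Psrc1 at 5.71 (SE 0.18) and the neutrophil chemokine Cxcl1 at 5.63 (SE 0.24). Among 39 measured p53 targets, 32 rose, 4 fell and 3 were not called (32 and 4 adjusted over the list alone). The median was 1.80 over the list (camera adjusted p = 4.4e-36, adjusted p = 0.019 with an estimated correlation). Phlda3, a repressor of Akt, reached 5.39 (SE 0.16), the nuclease Aen 2.78 (SE 0.08) and cyclin G1 (Ccng1) 2.62 (SE 0.07). Tubular injury genes numbered 30, of which 21 rose, 1 fell and 8 were not called (21 and 1 adjusted over the list alone). The median was 0.95 over the list (camera adjusted p = 5.7e-10, adjusted p = 0.16 with an estimated correlation). They included the stress cytokine Gdf15 at 4.83 (SE 0.22), the TWEAK receptor Tnfrsf12a at 4.04 (SE 0.14) and Lcn2, which encodes the urinary injury marker NGAL, at 2.83 (SE 0.29, adjusted p = 1.6e-06).

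Proximal tubule transport genes moved the other way. Of the 45 measured, 1 rose, 40 fell and 4 were not called (1 and 41 adjusted over the list alone). The median was -1.11 over the list (camera adjusted p = 1.1e-23, adjusted p = 0.16 with an estimated correlation). Slco1a6, an organic anion transporter, had a log2 fold change of -1.95, the monocarboxylate transporter Slc5a8 had -1.91, the dicarboxylate transporter Slc13a2 -2.21 and Slc27a2, a fatty acid transporter and acyl-CoA synthetase, -2.34. Male-biased kidney genes, a class that responds to androgens and is largely expressed in the proximal tubule, were 16, of which 0 rose, 16 fell and 0 were not called (0 and 16 adjusted over the list alone). The median was -1.51 over the list (camera adjusted p = 2.3e-12, adjusted p = 0.19 with an estimated correlation). Slc22a28 and Slc7a13 had log2 fold changes of -2.93 and -1.91. For cisplatin uptake, export and bioactivation (17 genes), 4 rose, 10 fell and 3 were not called (4 and 11 adjusted over the list alone). The median was -0.49 over the list (camera adjusted p = 0.030, adjusted p = 0.30 with an estimated correlation). The basolateral uptake carrier Slc22a2 had -0.92 (SE 0.08, adjusted p = 3.4e-07), the export carrier Slc47a1 -0.91 (SE 0.07) and the bioactivating enzyme Ggt1 -1.19 (SE 0.06), whereas the export pump Abcc2 rose by 1.65 (SE 0.08).

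Fuel metabolism fell in several lists. Among 15 gluconeogenesis genes, 2 rose, 11 fell and 2 were not called (2 and 11 adjusted over the list alone). The median was -0.81 over the list (camera adjusted p = 3.1e-06, adjusted p = 0.25 with an estimated correlation). Pck1, the rate-limiting enzyme of the pathway, fell from 1351 ± 282 to 171 ± 43.0 CPM, while pyruvate carboxylase (Pcx) had a log2 fold change of -2.48 (SE 0.09) and Fbp1 had -1.92 (SE 0.09). Citric acid cycle genes were 17, of which 0 rose, 15 fell and 2 were not called (0 and 15 adjusted over the list alone), with Suclg2 at -1.78 and Idh2 at -1.53. The median was -0.58 over the list (camera adjusted p = 4.1e-07, adjusted p = 0.25 with an estimated correlation). In the nuclear-encoded respiratory chain (71 genes), 0 rose, 65 fell and 6 were not called (0 and 66 adjusted over the list alone), with Ndufs1 of complex I at -0.89 and the ATP synthase subunit Atp5a1 at -0.66. The median was -0.44 over the list (camera adjusted p = 7.0e-08, adjusted p = 0.58 with an estimated correlation). Of 13 mitochondrially encoded genes, 0 rose, 13 fell and 0 were not called (0 and 13 adjusted over the list alone), with mt-Cytb at -0.99 and mt-Nd4 at -0.85. The median was -0.66 over the list (camera adjusted p = 1.2e-06, adjusted p = 0.25 with an estimated correlation). Genes of mitochondrial DNA took 11.35% to 12.18% of counts in cisplatin mice and 13.86% to 14.76% in saline mice. For the pyruvate dehydrogenase complex and its regulators, the target pathway of dichloroacetate, 1 rose, 12 fell and 1 was not called (2 and 12 adjusted over the list alone). The median was -0.46 over the list (camera adjusted p = 0.0026, adjusted p = 0.25 with an estimated correlation). Pdha1, the catalytic subunit, had -0.77, and of the 4 kinases Pdk1 had -0.62, Pdk2 -1.41 and Pdk3 -0.68, whereas Pdk4 rose from 12.6 ± 4.78 to 116 ± 28.2 CPM, a log2 fold change of 3.18 (SE 0.29, adjusted p = 5.7e-07).

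Fatty acid oxidation and PPARA target genes moved in both directions. Of 46 genes, 14 rose, 18 fell and 14 were not called (14 and 20 adjusted over the list alone), and the list's mean was 0.16, of opposite sign to its median and its camera direction. The median was -0.12 over the list (camera adjusted p = 0.83, adjusted p = 0.95 with an estimated correlation). The lipid droplet protein Plin2 rose from 14.0 ± 0.660 to 372 ± 43.1 CPM, the acyl-CoA thioesterases Acot1 and Acot2 had 1.71 and 1.66, and Cyp4a14, a fatty acid hydroxylase, had 2.96 (SE 0.40, adjusted p = 2.4e-05), or 2.29 without cisplatin replicate 3. Cpt1a, which admits fatty acids to the mitochondrion, fell with -0.90 (SE 0.07, adjusted p = 1.4e-07). Glycolysis genes (20) gave no list call, as 5 rose, 4 fell and 11 were not called (5 and 4 adjusted over the list alone). The median was 0.01 over the list (camera adjusted p = 0.80, adjusted p = 0.91 with an estimated correlation). Cholesterol synthesis (23 genes) included Cyp51 at -2.40, and 6 rose, 13 fell and 4 were not called (7 and 13 adjusted over the list alone). The median was -0.28 over the list (camera adjusted p = 0.030, adjusted p = 0.25 with an estimated correlation). Fatty acid synthesis (17 genes) included acetyl-CoA carboxylase Acaca at -2.03, and 2 rose, 10 fell and 5 were not called (2 and 10 adjusted over the list alone). The median was -0.37 over the list (camera adjusted p = 0.035, adjusted p = 0.25 with an estimated correlation).

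Stress and inflammatory programmes rose. Among 23 NRF2 targets, the antioxidant response, 19 rose, 1 fell and 3 were not called (20 and 2 adjusted over the list alone). The median was 0.94 over the list (camera adjusted p = 9.6e-17, adjusted p = 0.057 with an estimated correlation). Sulfiredoxin (Srxn1) had 2.81 (SE 0.07), Txnrd1 2.35 (SE 0.08) and Nqo1 2.32 (SE 0.05). Inflammatory cytokine and NF-kB response genes were 29, of which 21 rose, 2 fell and 6 were not called (21 and 2 adjusted over the list alone), with complement C3 at 3.40 and Nfkbiz at 2.06. The median was 1.47 over the list (camera adjusted p = 1.5e-09, adjusted p = 0.20 with an estimated correlation). Early response genes were 22, of which 19 rose, 1 fell and 2 were not called (19 and 1 adjusted over the list alone), with Fosl1 at 4.55, Junb at 3.07 and Myc at 2.96. The median was 1.57 over the list (camera adjusted p = 2.3e-11, adjusted p = 0.19 with an estimated correlation). Heat shock and metal response genes were 20, of which 14 rose, 2 fell and 4 were not called (14 and 3 adjusted over the list alone), with the chaperones Hspb1 at 2.21 and Bag3 at 0.90. The median was 0.55 over the list (camera adjusted p = 0.00017, adjusted p = 0.25 with an estimated correlation). Endoplasmic reticulum and integrated stress genes were 27, of which 15 rose, 7 fell and 5 were not called (15 and 7 adjusted over the list alone). The median was 0.36 over the list (camera adjusted p = 0.035, adjusted p = 0.25 with an estimated correlation). They split between Mthfd2, a folate enzyme, at 2.22 and Herpud1, of protein degradation at the reticulum, at -1.38.

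The remaining functional lists showed smaller or mixed changes. For glutathione transferases and glutathione metabolism (32 genes), 16 rose, 12 fell and 4 were not called (16 and 12 adjusted over the list alone), with Mgst1 at 2.17. The median was 0.14 over the list (camera adjusted p = 0.12, adjusted p = 0.72 with an estimated correlation). For proliferation (35 genes), 14 rose, 5 fell and 16 were not called (14 and 5 adjusted over the list alone), with the replication clamp Pcna at 0.79. The median was 0.38 over the list (camera adjusted p = 0.12, adjusted p = 0.72 with an estimated correlation). For apoptosis and regulated necrosis (28 genes), 13 rose, 5 fell and 10 were not called (14 and 5 adjusted over the list alone). The median was 0.19 over the list (camera adjusted p = 0.11, adjusted p = 0.25 with an estimated correlation). For the circadian clock (18 genes), 7 rose, 6 fell and 5 were not called (8 and 7 adjusted over the list alone), the mean being -0.02, and the clock repressor Cry1 had 2.54. The median was 0.09 over the list (camera adjusted p = 0.80, adjusted p = 0.91 with an estimated correlation). Cytosolic ribosomal protein genes were 52, of which 45 rose, 2 fell and 5 were not called (45 and 2 adjusted over the list alone), with Rplp0 at 0.64. The median was 0.29 over the list (camera adjusted p = 0.00028, adjusted p = 0.72 with an estimated correlation).

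Markers of other kidney cells and of blood cells moved as follows. Loop of Henle and distal tubule markers were 21, of which 3 rose, 15 fell and 3 were not called (3 and 15 adjusted over the list alone). The median was -0.63 over the list (camera adjusted p = 0.00016, adjusted p = 0.25 with an estimated correlation). The thiazide-sensitive transporter Slc12a3 had -2.79, Egf -2.84 and Pvalb -2.27. Collecting duct markers were 19, of which 1 rose, 13 fell and 5 were not called (1 and 14 adjusted over the list alone), with Aqp3 at -1.27 and Scnn1g at -0.50. The median was -0.42 over the list (camera adjusted p = 0.0075, adjusted p = 0.30 with an estimated correlation). Podocyte markers were 15, of which 1 rose, 8 fell and 6 were not called (1 and 8 adjusted over the list alone). The median was -0.33 over the list (camera adjusted p = 0.30, adjusted p = 0.77 with an estimated correlation). Endothelial markers were 18, of which 0 rose, 6 fell and 12 were not called (0 and 6 adjusted over the list alone). The median was -0.24 over the list (camera adjusted p = 0.26, adjusted p = 0.86 with an estimated correlation). Macrophage markers were 25, of which 3 rose, 9 fell and 13 were not called (2 and 8 adjusted over the list alone). The median was -0.39 over the list (camera adjusted p = 0.82, adjusted p = 0.95 with an estimated correlation). Cd68 and Cd14 rose by 4.00 and 2.31, while Csf1r had -0.87. Neutrophil markers with enough counts were 7, of which 3 rose, 0 fell and 4 were not called (3 and 0 adjusted over the list alone), and S100a8 and S100a9 rose to 0.422 and 0.821 CPM from 0.116 and 0.240 CPM in saline. The median was 0.66 over the list (camera adjusted p = 0.12, adjusted p = 0.25 with an estimated correlation). Lymphocyte markers were 12, of which 0 rose, 4 fell and 8 were not called (0 and 2 adjusted over the list alone). The median was -0.43 over the list (camera adjusted p = 0.74, adjusted p = 0.86 with an estimated correlation). Fibroblast and smooth muscle markers were 21, of which 0 rose, 8 fell and 13 were not called (0 and 0 adjusted over the list alone). The median was -0.49 over the list (camera adjusted p = 0.26, adjusted p = 0.79 with an estimated correlation). Adipocyte markers were 12, of which 2 rose, 3 fell and 7 were not called (2 and 3 adjusted over the list alone), and the camera direction was down although median and mean (0.61) were positive. The median was 0.58 over the list (camera adjusted p = 0.53, adjusted p = 0.86 with an estimated correlation). Erythroid genes were 8, of which 1 rose, 5 fell and 2 were not called (1 and 5 adjusted over the list alone), with Alas2 at -2.08. The median was -2.13 over the list (camera adjusted p = 0.25, adjusted p = 0.72 with an estimated correlation).

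Among named genes with at least 5 CPM in the higher group, the 8 largest falls were in long genes and in mitochondrial transfer RNAs. Fhit, a dinucleoside hydrolase gene on chromosome 14, 9550092 to 11162035, had -5.61 (SE 0.23), the mitochondrial carrier Slc25a21 on chromosome 12, 56712634 to 57197472 had -5.47 (SE 0.20) and the potassium channel Kcnh1 had -4.40 (SE 0.43). By genomic span, the median log2 fold change was 0.13 in 5469 genes of up to 5 kb, -0.42 in 1301 genes of 100 to 200 kb and -1.39 in 243 genes above 400 kb. The medians in the combination against dichloroacetate were 0.08, -0.19 and -1.03 in the same bins, and those in dichloroacetate against saline were 0, 0.01 and -0.01. The transfer RNAs mt-Tk, mt-Td, mt-Tg, mt-Tr and mt-Th had -5.45 (SE 1.03), -5.31 (SE 1.24), -5.22 (SE 0.81), -5.01 (SE 0.81) and -4.06 (SE 0.50). Without saline replicate 3 these were -4.31, -2.89, -4.55, -4.32 and -3.40, all still called. These sizes thus depend on that library, and mt-Td had -7.13 without cisplatin replicate 2. Their levels varied widely among saline mice, with mt-Td at 260.2 ± 367 CPM, and mitochondrial transfer RNAs took 0.785% of counts in saline replicate 3 against 0.18% to 0.533% in the other libraries.

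**Figure D2:**
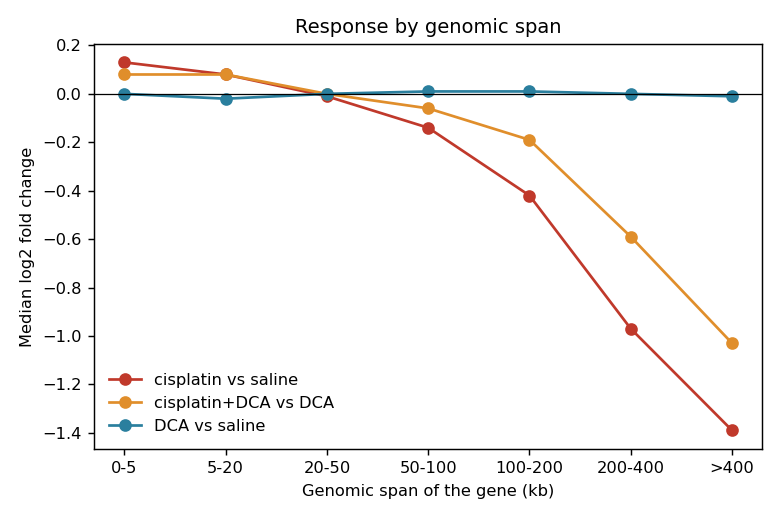
Median log2 fold change (vertical axis) of tested genes grouped by genomic span in kb (horizontal axis), for 3 comparisons drawn as lines. Cisplatin against saline runs from 0.13 in the shortest genes to -1.39 in those above 400 kb, and dichloroacetate against saline stays between -0.02 and 0.01.

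Dichloroacetate alone was compared with saline to describe its effect on the uninjured kidney. Few genes changed: 26 rose and 37 fell, 0.3% of those tested, and 1 of them changed by at least 1 log2 unit, while 2427 genes had an unadjusted p below 0.05. That gene was Dpys, dihydropyrimidinase of pyrimidine breakdown, which fell from 6.11 ± 1.11 to 1.85 ± 0.223 CPM (SD, n = 3), a log2 fold change of -1.73 (SE 0.18, adjusted p = 0.0022). Pzp, a protease inhibitor of the alpha-2-macroglobulin family on chromosome 6, 128483567 to 128526720, had the smallest adjusted p of all tested genes and fell from 157 ± 2.74 to 90.4 ± 4.88 CPM, a log2 fold change of -0.80 (SE 0.06, adjusted p = 0.00019). Cry1 rose by 0.98 (SE 0.10, adjusted p = 0.0025), and Odc1, the rate-limiting enzyme of polyamine synthesis, by 0.89 (SE 0.15, adjusted p = 0.031). DESeq2 called 336 genes, and the edgeR count was 126 without saline replicate 3, 22 without saline replicate 1, 21 without saline replicate 2, 16 without dichloroacetate replicate 1 and 33 without dichloroacetate replicate 3.

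Further rises were the lysosomal enzyme Gusb at 0.92 (SE 0.17), the medium-chain acyl-CoA synthetase Acsm3 at 0.89 (SE 0.11), the exonuclease Eri2 at 0.87 (SE 0.10), the nuclear noncoding RNA Malat1 at 0.66 (SE 0.08), the coenzyme A hydrolase Nudt19 at 0.65 (SE 0.12), the ether lipid enzyme Agps at 0.54 (SE 0.10) and Tmigd1 at 0.52 (SE 0.08). Acsm3 and Eri2 overlap on opposite strands of chromosome 7, and without strand information their rises cannot be separated. Falls included the tight junction protein Cgn at -0.91 (SE 0.17), the efflux pump Abcb1b at -0.75 (SE 0.14), the ethanolamine phosphate phospho-lyase Etnppl at -0.73 (SE 0.13), apolipoprotein Apoe at -0.71 (SE 0.09), Nav2 at -0.66 (SE 0.12) and the fatty acid binding protein Fabp7 at -0.66 (SE 0.11). The amino acid transporters Slc7a9 and Slc7a7 fell, with -0.41 and -0.43, as did Acsl1 and Acot1 of fatty acid metabolism with -0.54 and -0.44, Mgst1 and Gstt1 with -0.48 and -0.42, and cyclin D1 (Ccnd1) with -0.45, while Ccng1 rose by 0.40. Among the kinases that dichloroacetate inhibits, Pdk3 rose by 0.35 (SE 0.06, adjusted p = 0.041), and Pdk1, Pdk2 and Pdk4 had 0.12 (SE 0.10, adjusted p = 0.70), -0.10 (SE 0.07, adjusted p = 0.66) and -0.48 (SE 0.30, adjusted p = 0.56). The genes Havcr1, Lcn2, Cdkn1a, Slc34a1, Slc22a2, Cpt1a and Cyp4a14 were not called, with log2 fold changes of 0.53 (SE 0.11, adjusted p = 0.072), 0.07, -0.48, -0.15, 0.04, -0.10 and -0.42 (SE 0.44, adjusted p = 0.76). Of all 38 genes named for this comparison 28 were called, and 20 of these lost their call under at least 1 alternative.

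Camera called 15 of 34 lists with dichloroacetate, 10 up and 5 down. With an estimated correlation 0 were called (2 at an unadjusted p below 0.05, lowest adjusted p = 0.486), and fry called 0 (5 unadjusted). Other splits of the same 6 mice gave up to 21 camera calls. The downward calls numbered 2 without saline replicate 3 and 3 without dichloroacetate replicate 2. Of the 15 lists, those of the respiratory chain, male-biased genes, heat shock, mitochondrially encoded genes and endoplasmic reticulum stress kept their camera call without each single library. All 5 downward lists lost theirs without at least 1 library, and the camera direction of endothelial markers turned up without saline replicate 1. The respiratory chain had a median of 0.12 (camera adjusted p = 3.7e-13, adjusted p = 0.73 with an estimated correlation), without any of its 71 members called over all genes or adjusted over the list alone. Male-biased genes had a median of 0.21 (camera adjusted p = 1.5e-07, adjusted p = 0.49 with an estimated correlation), with 2 of 16 members called higher, and 3 higher and 1 lower adjusted over the list alone. Heat shock genes had a median of 0.19 (camera adjusted p = 1.5e-07, adjusted p = 0.49 with an estimated correlation), with 0 of 20 members called and 2 higher adjusted over the list alone. Mitochondrially encoded genes had a median of 0.14 (camera adjusted p = 3.0e-07, adjusted p = 0.49 with an estimated correlation), with 0 of 13 called and 8 higher adjusted over the list alone. The pyruvate dehydrogenase list had a median of 0.10 (camera adjusted p = 0.0080, adjusted p = 0.62 with an estimated correlation), with 1 of 14 called and 2 adjusted over the list alone. Fatty acid oxidation genes had a median of -0.04 (camera adjusted p = 0.016, adjusted p = 0.78 with an estimated correlation), with 1 higher and 2 lower of 46, and 3 and 9 adjusted over the list alone. Camera called markers of 3 other kidney cell types lower, without any member called over all genes or adjusted over the list alone. Collecting duct markers (19) had a median of -0.07 (camera adjusted p = 0.0085, adjusted p = 0.69 with an estimated correlation). Podocyte markers (15) had a median of -0.10 (camera adjusted p = 0.016, adjusted p = 0.73 with an estimated correlation). Endothelial markers (18) had a median of -0.13 (camera adjusted p = 0.029, adjusted p = 0.82 with an estimated correlation). Adipocyte markers (12) had a higher median of 0.43 (camera adjusted p = 0.037, adjusted p = 0.78 with an estimated correlation), with 0 called. Citric acid cycle genes had a median of 0.08 (camera adjusted p = 0.023, adjusted p = 0.78 with an estimated correlation), with 0 of 17 called. Stress genes of the endoplasmic reticulum had a median of 0.14 (camera adjusted p = 0.00087, adjusted p = 0.49 with an estimated correlation), with 0 of 27 called, and 6 higher and 1 lower adjusted over the list alone. Circadian clock genes had a median of 0.13 (camera adjusted p = 0.0085, adjusted p = 0.65 with an estimated correlation), with 1 of 18 called and 2 adjusted over the list alone. Cholesterol synthesis genes had a median of 0.07 (camera adjusted p = 0.0085, adjusted p = 0.49 with an estimated correlation), with 0 of 23 called, and 4 higher and 1 lower adjusted over the list alone. Glutathione genes had a median of -0.09 (camera adjusted p = 0.0085, adjusted p = 0.78 with an estimated correlation), with 2 of 32 lower, and 2 higher and 6 lower adjusted over the list alone. The tubular injury list was not called, with a median of -0.01 (camera adjusted p = 0.37, adjusted p = 0.83 with an estimated correlation) and a mean of 0.16, of opposite sign to the median. Median and mean also differed in sign for lymphocyte markers (-0.01 and 0.09), fibroblast and smooth muscle markers (-0.004 and 0.09) and cisplatin uptake genes (0.04 and -0.04), and erythroid genes had a median of -0.02 with an upward camera direction.

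The combination was compared with cisplatin alone to see how dichloroacetate changed the injured kidney. Krt20 was at 4.48 ± 0.554 CPM in the combination and 43.8 ± 3.62 CPM with cisplatin alone (SD, n = 3), a log2 fold change of -3.29 (SE 0.19, adjusted p = 7.5e-07). Havcr1 was lower, at 82.3 ± 12.4 CPM (-0.89, SE 0.11, adjusted p = 6.0e-05), as was Cdkn1a, at 175 ± 28.5 CPM (-1.11, SE 0.16, adjusted p = 0.00017). Pck1 was higher, at 758 ± 126 against 171 ± 43.0 CPM (2.15, SE 0.20, adjusted p = 8.5e-06), and Slc34a1 was at 1487 ± 93.0 CPM (0.81, SE 0.07, adjusted p = 4.3e-06). Lcn2, at 4.67 ± 0.675 CPM, did not pass the test (-0.52, SE 0.24, adjusted p = 0.13). Of 20370 genes, 3688 were higher and 2753 lower in the combination, 31.6% of those tested, and 609 differed by at least 1 log2 unit. Camera called 18 of 34 lists, 10 up and 8 down, against 0 with an estimated correlation (8 at an unadjusted p below 0.05) and 21 with fry, and other splits of these 6 mice gave up to 19.

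**Figure D3:**
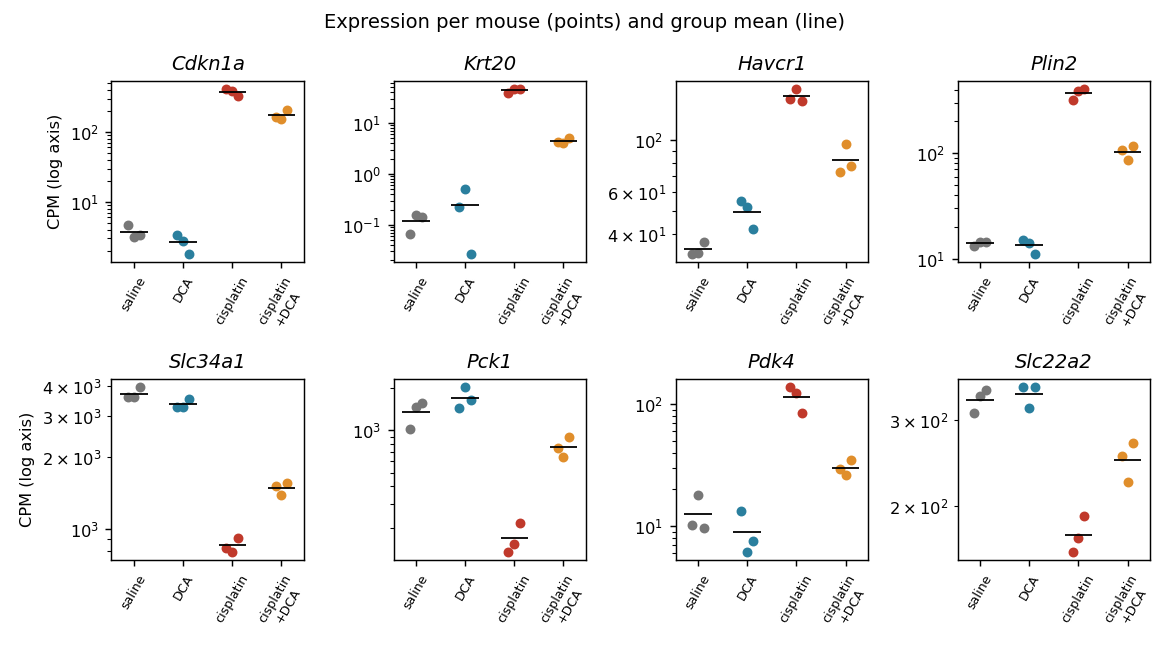
CPM on a log axis for 8 genes, with 1 point per mouse, 3 mice per group and a line at each group mean. Krt20 averages 43.8 CPM with cisplatin and 4.48 CPM in the combination, and Pck1 averages 171 CPM and 758 CPM.

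The proximal tubule transport list was higher in the combination, where of 45 genes 40 rose, 0 fell and 5 were not called (41 and 0 adjusted over the list alone). The median was 0.66 over the list (camera adjusted p = 3.7e-30, adjusted p = 0.12 with an estimated correlation). The endocytic receptor Cubn had 1.36 (SE 0.11), Slc13a2 1.56 (SE 0.10), Slc27a2 1.15 (SE 0.11) and Slc22a2 0.51 (SE 0.08, adjusted p = 0.00029). Male-biased genes were 16, of which 14 rose, 0 fell and 2 were not called (14 and 0 adjusted over the list alone), with Slc22a28 at 1.16 and Acsm3 at 0.98. The median was 0.71 over the list (camera adjusted p = 8.9e-11, adjusted p = 0.18 with an estimated correlation). Gluconeogenesis genes were 15, of which 12 rose, 0 fell and 3 were not called (12 and 0 adjusted over the list alone), with Fbp1 at 0.94. The median was 0.41 over the list (camera adjusted p = 9.4e-10, adjusted p = 0.21 with an estimated correlation). Citric acid cycle genes were 17, of which 16 rose, 0 fell and 1 was not called (17 and 0 adjusted over the list alone), with Sdhb at 0.55. The median was 0.38 over the list (camera adjusted p = 1.4e-08, adjusted p = 0.28 with an estimated correlation). In the nuclear-encoded respiratory chain, 67 rose, 0 fell and 4 were not called (69 and 0 adjusted over the list alone), with Uqcrfs1 at 0.43. The median was 0.33 over the list (camera adjusted p = 1.1e-15, adjusted p = 0.42 with an estimated correlation). Mitochondrially encoded genes were 13, of which 13 rose, 0 fell and 0 were not called (13 and 0 adjusted over the list alone), with mt-Nd4 at 0.28, and mitochondrial DNA took 12.02% to 12.54% of counts in the combination. The median was 0.22 over the list (camera adjusted p = 0.0020, adjusted p = 0.45 with an estimated correlation).

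In the pyruvate dehydrogenase list, 12 rose, 1 fell and 1 was not called (12 and 1 adjusted over the list alone). The median was 0.29 over the list (camera adjusted p = 0.00040, adjusted p = 0.21 with an estimated correlation). Pdha1 was higher by 0.41 (SE 0.05), Pdk1 by 0.47 (SE 0.10, adjusted p = 0.0035), Pdk2 by 0.77 (SE 0.07, adjusted p = 1.0e-05) and Pdk3 by 0.30 (SE 0.07, adjusted p = 0.0029). Pdk4 was lower, at 30.1 ± 4.44 against 116 ± 28.2 CPM (-1.94, SE 0.27, adjusted p = 0.00014). For fatty acid oxidation and PPARA targets, 25 rose, 5 fell and 16 were not called (26 and 5 adjusted over the list alone). The median was 0.29 over the list (camera adjusted p = 0.00017, adjusted p = 0.45 with an estimated correlation). Cpt1a was higher by 0.49 (SE 0.07, adjusted p = 0.00016) and Plin2 was lower, at -1.85 (SE 0.12), while Cyp4a14 at -0.03 (SE 0.35, adjusted p = 0.97) was not called, nor at 0.64 without cisplatin replicate 3. Cisplatin uptake, export and bioactivation genes were 17, of which 10 rose, 1 fell and 6 were not called (10 and 1 adjusted over the list alone). The median was 0.51 over the list (camera adjusted p = 3.3e-05, adjusted p = 0.13 with an estimated correlation). Ggt1 had 0.56 and Gstz1, which also metabolises dichloroacetate, had 0.73.

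Injury, stress and inflammatory lists were lower in the combination. Tubular injury genes were 30, of which 0 rose, 16 fell and 14 were not called (0 and 17 adjusted over the list alone), with the cornified envelope protein Sprr1a at -2.34 and Tnfrsf12a at -1.49. The median was -0.54 over the list (camera adjusted p = 1.4e-12, adjusted p = 0.12 with an estimated correlation). Among p53 targets, 5 rose, 25 fell and 9 were not called (6 and 27 adjusted over the list alone), with Btg2 at -1.47, Pmaip1 at -1.57 and Mdm2 at -0.63. The median was -0.35 over the list (camera adjusted p = 1.6e-09, adjusted p = 0.13 with an estimated correlation). Sfn, which encodes 14-3-3 sigma, had -2.30 (SE 0.17). Early response genes were 22, of which 1 rose, 15 fell and 6 were not called (1 and 16 adjusted over the list alone), with Fosl1 at -3.47 (SE 0.11), Egr1 at -2.35 (SE 0.26), Junb at -1.59 and Myc at -1.60. The median was -0.99 over the list (camera adjusted p = 4.4e-16, adjusted p = 0.12 with an estimated correlation). In the inflammatory list, 2 rose, 17 fell and 10 were not called (2 and 20 adjusted over the list alone), with the chemokines Cxcl10 at -2.54 (SE 0.35) and Cxcl1 at -2.01 (SE 0.18) and Tnfaip3 at -1.04. The median was -0.85 over the list (camera adjusted p = 2.5e-11, adjusted p = 0.13 with an estimated correlation). NRF2 targets were 23, of which 1 rose, 11 fell and 11 were not called (1 and 12 adjusted over the list alone), with heme oxygenase Hmox1 at -1.57 and Srxn1 at -1.43. The median was -0.28 over the list (camera adjusted p = 4.2e-11, adjusted p = 0.12 with an estimated correlation). In the heat shock list, 1 rose, 7 fell and 12 were not called (1 and 7 adjusted over the list alone), with Hspb1 at -1.15. The median was -0.07 over the list (camera adjusted p = 0.0030, adjusted p = 0.42 with an estimated correlation). The stress factor Atf3 had -2.09, although in its list, of the reticulum and integrated stress response, 6 rose, 10 fell and 11 were not called (7 and 10 adjusted over the list alone). The median was -0.05 over the list (camera adjusted p = 0.17, adjusted p = 0.45 with an estimated correlation). Macrophage markers were 25, of which 0 rose, 3 fell and 22 were not called (0 and 2 adjusted over the list alone), with Cd68 at -2.77 (SE 0.22) and Cd14 at -1.10 (SE 0.15). The median was -0.17 over the list (camera adjusted p = 0.044, adjusted p = 0.72 with an estimated correlation). For proliferation, 2 rose, 9 fell and 24 were not called (2 and 9 adjusted over the list alone), with Pcna at -0.56. The median was -0.18 over the list (camera adjusted p = 0.013, adjusted p = 0.49 with an estimated correlation).

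Among the largest differences, the kinase scaffold Ksr2 was higher by 2.33 (SE 0.20), Ldlrad3 by 1.85 (SE 0.10), the thyroid hormone receptor Thrb by 1.64 (SE 0.16), Snx29 by 1.62 (SE 0.13), the G protein Gna14 by 1.52 (SE 0.12) and adenosine kinase Adk by 1.49 (SE 0.12). Olfr1442 was lower, at -3.71 (SE 1.00), but its 5.17 ± 7.69 CPM in cisplatin rested on 1 library, at 14.0 CPM against 0.682 and 0.773 in the others. It had -0.86 without that library, cisplatin replicate 3, and lost its call under limma-voom. In the clock list, 7 rose, 3 fell and 8 were not called (7 and 3 adjusted over the list alone), with Hlf at 1.32 and Cry1 at -0.90. The median was 0.43 over the list (camera adjusted p = 0.046, adjusted p = 0.45 with an estimated correlation). The stress response list of the reticulum and the following lists were not called by camera. Collecting duct markers had 6 up and 0 down of 19 (6 and 0 adjusted over the list alone), with a median of 0.15 and a camera adjusted p = 0.085. Neutrophil markers had 0 up and 2 down of 7 (0 and 1 adjusted over the list alone), with a median of -0.52 and a camera adjusted p = 0.082, and podocyte markers 0 up and 1 down of 15 (0 and 1 adjusted over the list alone), with a median of -0.01 and a camera adjusted p = 0.23. Endothelial markers had 0 up and 0 down of 18 (0 and 0 adjusted over the list alone), with a median of -0.08 and a camera adjusted p = 0.36. Fibroblast and smooth muscle markers had 0 up and 0 down of 21 (0 and 0 adjusted over the list alone), with a median of -0.11 and a camera adjusted p = 0.42. Loop of Henle and distal tubule markers had 5 up and 3 down of 21 (5 and 3 adjusted over the list alone), with a median of 0.14 and a camera adjusted p = 0.37. Lymphocyte markers had 0 up and 0 down of 12 (0 and 0 adjusted over the list alone), with a median of -0.01 and a camera adjusted p = 0.80, and adipocyte markers 2 up and 0 down of 12 (2 and 0 adjusted over the list alone), with a median of 0.18 and a camera adjusted p = 0.40. Erythroid genes had 0 up and 0 down of 8 (0 and 0 adjusted over the list alone), with a median of 0.20 and a camera adjusted p = 0.77. Apoptosis and necrosis genes had 3 up and 8 down of 28 (4 and 8 adjusted over the list alone), with a median of -0.10 and a camera adjusted p = 0.096. Glutathione genes had 13 up and 4 down of 32 (13 and 4 adjusted over the list alone), with a median of 0.11 and a camera adjusted p = 0.12. Fatty acid synthesis had 7 up and 2 down of 17 (7 and 3 adjusted over the list alone), with a median of 0.20 and a camera adjusted p = 0.21. Cholesterol synthesis had 7 up and 4 down of 23 (7 and 4 adjusted over the list alone), with a median of 0.02 and a camera adjusted p = 0.62. Glycolysis had 4 up and 2 down of 20 (4 and 2 adjusted over the list alone), with a median of -0.01 and a camera adjusted p = 0.90, and ribosomal proteins 2 up and 1 down of 52 (0 and 1 adjusted over the list alone), with a median of -0.02 and a camera adjusted p = 0.36. Median and mean differed in sign for loop of Henle and distal tubule markers (mean -0.05) and lymphocyte markers (mean 0.04), and the camera direction of glycolysis was up.

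Cisplatin with saline and the combination with cisplatin share the cisplatin mice, so their fold changes are negatively related even without an effect. Genes called higher with cisplatin and lower in the combination numbered 2582, and those called lower and then higher numbered 3231. Independent lists of the same sizes would share 817 and 1122. Groups simulated without any effect shared 0, a value fixed by the lack of calls to share, which sets no level for these counts. Across genes, which are not independent replicates, the correlation was -0.737 against -0.503 in the simulation, and the covariance was -0.3077 against -0.0224. Part of the excess may come from the shared mice.

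The combination was also compared with dichloroacetate alone, for the response to cisplatin in mice given dichloroacetate. It shares no library with cisplatin against saline. Dichloroacetate days differed too (5 against 6), which neither this comparison nor the interaction separates from cisplatin. Here 4377 genes rose and 3909 fell, 40.7% of those tested. Cdkn1a rose by 6.02 (SE 0.21, adjusted p = 2.9e-10), Havcr1 by 0.73 (SE 0.11, adjusted p = 0.00016), Lcn2 by 2.24 (SE 0.29, adjusted p = 4.1e-05), Pdk4 by 1.71 (SE 0.29, adjusted p = 0.00039) and Cyp4a14 by 3.36 (SE 0.41, adjusted p = 2.5e-05). Falls were -1.18 (SE 0.07, adjusted p = 2.5e-08) for Slc34a1, -0.45 (SE 0.08, adjusted p = 0.00051) for Slc22a2, -0.31 (SE 0.07, adjusted p = 0.0032) for Cpt1a, -0.54 (SE 0.07, adjusted p = 6.0e-05) for Pdk2, -0.72 (SE 0.06, adjusted p = 1.3e-06) for Pdk3 and -0.27 (SE 0.10, adjusted p = 0.046) for Pdk1, the last of which lost its call under 7 alternatives. Among p53 targets, 29 rose, 3 fell and 7 were not called (29 and 3 adjusted over the list alone). The median was 1.39 over the list (camera adjusted p = 1.4e-49, adjusted p = 0.0031 with an estimated correlation). For proximal tubule transport, 5 rose, 32 fell and 8 were not called (5 and 32 adjusted over the list alone). The median was -0.52 over the list (camera adjusted p = 1.7e-09, adjusted p = 0.32 with an estimated correlation). For tubular injury, 13 rose, 2 fell and 15 were not called (13 and 2 adjusted over the list alone). The median was 0.26 over the list (camera adjusted p = 3.6e-05, adjusted p = 0.32 with an estimated correlation). Of 13 mitochondrially encoded genes, 0 rose, 13 fell and 0 were not called (0 and 13 adjusted over the list alone). The median was -0.56 over the list (camera adjusted p = 7.3e-11, adjusted p = 0.19 with an estimated correlation). Cisplatin uptake genes had a median of -0.04 and a mean of 0.04, of opposite sign. Against saline, the combination changed 8189 genes, 4203 higher and 3986 lower, with Krt20 at 5.17 (SE 0.36, adjusted p = 1.6e-07), Havcr1 at 1.26 (SE 0.11, adjusted p = 1.5e-06), Cdkn1a at 5.55 (SE 0.20, adjusted p = 4.4e-10), Pck1 at -0.83 (SE 0.19, adjusted p = 0.0037) and Slc34a1 at -1.32 (SE 0.07, adjusted p = 9.0e-09).

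The interaction tested whether the response to cisplatin differed with dichloroacetate. It was called for 3783 genes, 2327 of them higher and 1456 lower, which is 18.6% of those tested. The 10 smallest adjusted p values belonged to Fosl1 at -3.24 (SE 0.20, adjusted p = 9.2e-06), Srxn1 at -1.28 (SE 0.09, adjusted p = 9.4e-06), Dennd1a at 1.44 (SE 0.10, adjusted p = 9.4e-06), the mitochondrial carrier Sfxn5 at 1.21 (SE 0.09), Cry1 at -1.88 (SE 0.14), the retinal reductase Dhrs3 at 1.31 (SE 0.10), the SMAD corepressor Skil at -0.81 (SE 0.06), the inflammasome sensor Nlrp6 at 1.31 (SE 0.10), Ldlrad3 at 1.69 (SE 0.14) and the nuclear import receptor Kpna2 at -0.76 (SE 0.06). The rise of Havcr1 was smaller with dichloroacetate, with an interaction of -1.43 (SE 0.16, adjusted p = 9.9e-05), as was that of Pdk4 (-1.47, SE 0.40, adjusted p = 0.021). The falls of Slc34a1 (0.96, SE 0.10, adjusted p = 7.0e-05), Slc22a2 (0.47, SE 0.11, adjusted p = 0.010), Cpt1a (0.59, SE 0.10, adjusted p = 0.0014) and Pdk2 (0.87, SE 0.10, adjusted p = 0.00016) were smaller too. The interactions of Cdkn1a (-0.63, SE 0.27, adjusted p = 0.12), Lcn2 (-0.59, SE 0.42, adjusted p = 0.37), Pdk1 (0.35, SE 0.14, adjusted p = 0.10), Pdk3 (-0.04, SE 0.09, adjusted p = 0.81) and Cyp4a14 (0.39, SE 0.56, adjusted p = 0.69) did not pass the test. The interaction of Pdk4 lost its call under 4 alternatives.

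Camera called 19 of 34 lists in the interaction, 10 up and 9 down, against 0 with an estimated correlation (8 at an unadjusted p below 0.05, lowest adjusted p = 0.179) and 18 with fry. For proximal tubule transport, 39 members were higher, 0 lower and 6 not called (39 and 1 adjusted over the list alone). The median was 0.61 over the list (camera adjusted p = 6.9e-31, adjusted p = 0.18 with an estimated correlation). For tubular injury, 0 members were higher, 12 lower and 18 not called (0 and 14 adjusted over the list alone). The median was -0.67 over the list (camera adjusted p = 8.6e-10, adjusted p = 0.18 with an estimated correlation). For early response genes, 0 members were higher, 11 lower and 11 not called (0 and 12 adjusted over the list alone). The median was -0.81 over the list (camera adjusted p = 1.5e-10, adjusted p = 0.18 with an estimated correlation). For p53 targets, 4 members were higher, 20 lower and 15 not called (6 and 27 adjusted over the list alone). The median was -0.45 over the list (camera adjusted p = 4.7e-08, adjusted p = 0.18 with an estimated correlation). Among lists without a call, median and mean differed in sign for glycolysis (0.05 and -0.03), cholesterol synthesis (0.03 and -0.07) and adipocyte markers (0.01 and -0.86), and podocyte and endothelial markers had medians of 0.08 and 0.05 with a downward camera direction. Other arrangements of the mice gave up to 24 camera calls.

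**Figure D4:**
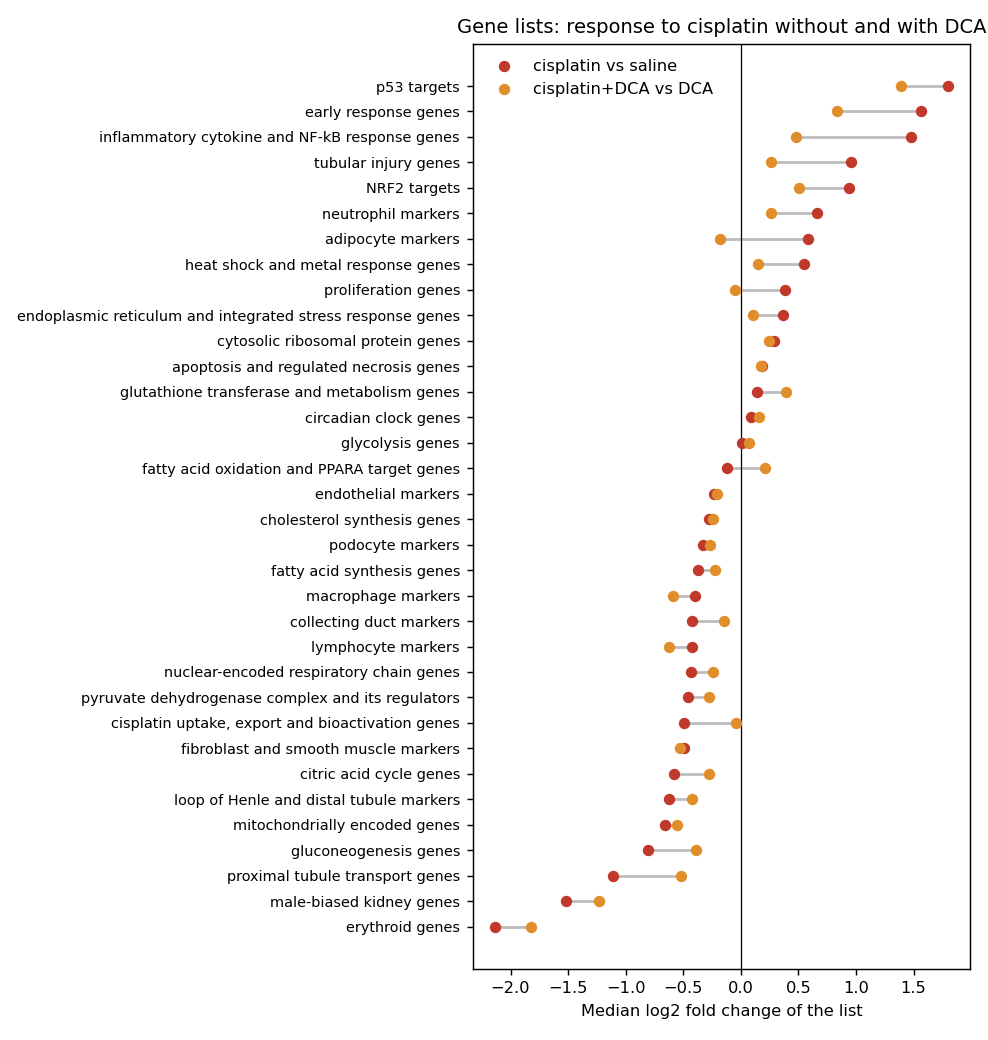
Median log2 fold change (horizontal axis) of each tested gene list for cisplatin against saline and for the combination against dichloroacetate, with the points of a list joined by a line. The median of p53 targets is 1.80 without and 1.39 with dichloroacetate, and that of proximal tubule transport genes is -1.11 and -0.52.

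Over the 12951 genes called for the mean cisplatin effect, the median interaction signed by that effect was -0.207 log2 units, with -0.16 in genes that rose and -0.266 in genes that fell. The exact 2-sided permutation test gave p = 0.1 (n = 3 mice per group), which does not pass the threshold. The response was smaller with dichloroacetate in 79.1% of these genes. Across genes, which are not independent replicates, the slope of the response with dichloroacetate on that without it was 0.694 and the correlation 0.894.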

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

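The depth test of the smaller response was chosen only after the result was seen, and the common-factor test and the splits were chosen before. All values here come from the interaction. It was called for 3783 genes, and among the named genes for 93, of which 51 had a positive and 42 a negative difference on the log2 scale. A positive value means that the log2 response to cisplatin was higher with dichloroacetate, and a negative value that it was lower. Either can also come from a change with dichloroacetate alone. Dpys had 4.892 to 7.073 CPM in saline and 1.695 to 2.103 in dichloroacetate. It had 1.988 to 2.95 CPM in cisplatin and 1.706 to 2.373 in the combination, with no higher level there. Other genes listed below were also called in dichloroacetate against saline, among them Pzp, Odc1, Malat1 and Cry1.

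The largest positive differences were Slc25a21 2.68, Ksr2 2.46, Snx29 1.84, Pck1 1.81, Ldlrad3 1.69, Cubn 1.55, Adk 1.53, Thrb 1.51, Slc13a2 1.49, Dpys 1.46, Dennd1a 1.44, Etnppl 1.34, Hlf 1.34 and Dhrs3 1.31. Smaller positive differences were found for Nlrp6 1.31, Nav2 1.25, Gna14 1.23, Sfxn5 1.21, Slc7a7 1.14, Slc27a2 1.11, Pcx 1.09, Ccnd1 1.05, Slc22a28 1.05, Slc34a1 0.96, Acsl1 0.91, Herpud1 0.90, Fbp1 0.89 and Acaca 0.87. Below these lay Pdk2 0.87, Slc7a9 0.87, Pzp 0.75, Slco1a6 0.73, Suclg2 0.73, Pvalb 0.71, Gstz1 0.70, Idh2 0.69, Cpt1a 0.59, Gstt1 0.58, Slc47a1 0.55, Slc12a3 0.53, Slc7a13 0.51 and Aqp3 0.47. The smallest positive values were Ggt1 0.47, Slc22a2 0.47, Slc5a8 0.47, Cyp51 0.40, Sdhb 0.40, Pdha1 0.32, Atp5a1 0.30, Ndufs1 0.30 and Uqcrfs1 0.28.

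The most negative differences were Krt20 -4.33, Fosl1 -3.24, Cxcl10 -2.71, Cd68 -2.58, Cxcl1 -2.50, Atf3 -2.38, Sprr1a -2.09, Egr1 -2.07, Sfn -1.98, Cry1 -1.88, Serpina7 -1.80, Plin2 -1.79, Tnfrsf12a -1.76 and Hmox1 -1.66. Less negative differences were found for Pmaip1 -1.54, Pdk4 -1.47, Btg2 -1.44, Havcr1 -1.43, Junb -1.30, Myc -1.30, Srxn1 -1.28, Hspb1 -1.23, Mthfd2 -1.18, Tnfaip3 -1.05, Gdf15 -1.03, Txnrd1 -1.02, Cd14 -0.98 and Phlda3 -0.86. Next came C3 -0.83, Skil -0.81, Bag3 -0.80, Nfkbiz -0.80, Odc1 -0.77, Kpna2 -0.76, Malat1 -0.76, Mdm2 -0.74, Eda2r -0.73, Abcc2 -0.72, Aen -0.65, Ccng1 -0.44, Pcna -0.43 and Nqo1 -0.32. Leaving out 1 library moved Krt20 to -3.56 (without dichloroacetate replicate 2) and Cxcl10 to -2.09 (without dichloroacetate replicate 1). The calls of Pdk4, Eda2r, Gdf15, Slc12a3, Ndufs1, Phlda3, Odc1, Cyp51, Uqcrfs1 and C3 were lost under at least 1 alternative.

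The median interactions of the 19 lists called by camera were -0.45 for p53 targets, -0.67 for tubular injury, 0.61 for proximal tubule transport, 0.30 for fatty acid oxidation and PPARA targets, 0.51 for gluconeogenesis, 0.18 for the pyruvate dehydrogenase complex and 0.32 for the citric acid cycle. They were 0.22 for the nuclear-encoded respiratory chain, -0.29 for NRF2 targets, 0.15 for glutathione transferases and metabolism, -0.80 for the inflammatory response, -0.24 for endoplasmic reticulum and integrated stress and -0.34 for proliferation. The rest were -0.30 for heat shock, 0.30 for collecting duct markers, -0.23 for macrophage markers, 0.51 for male-biased genes, -0.81 for early response genes and 0.47 for cisplatin uptake, export and bioactivation. None was called with an estimated correlation (8 at an unadjusted p below 0.05), and fry called 18 of 34 lists. Of 80 drawn arrangements 12, the true one included, gave as many camera calls as the 19, the highest giving 24, and of the 8 that kept the cisplatin and the combination mice each together 3 did.

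For the 3783 genes, 2 of 80 drawn arrangements gave as many calls, the true one included, and the other gave 4563. The gene share does not bear on chance, because mixing cisplatin with combination mice puts their difference into the residual spread. Such arrangements gave 0 gene calls but up to 24 list calls, so 19 lists do not stand out. Of 8 that kept each group together, too few for a share under 0.05, 2 gave as many gene calls.

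The pattern weighed here is the smaller response with dichloroacetate, a median signed interaction of -0.207 whose exact permutation p was 0.1. Thinning every library to the lowest total hardly tests lower depth, which both cisplatin groups shared. It gave -0.208 (SD 0.0013 over 20 thinnings). A single factor of 0.694 for every gene is argued against. After it was applied, 6.6% of tested genes (939 higher and 408 lower) were still called. A lower delivered dose or a later onset of injury in the combination mice may give a smaller response as well and was not tested. Protection by dichloroacetate stays open as a hypothesis, which the permutation p does not establish.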

How the results depend on the processing

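Only the removal of mitochondrially encoded genes was chosen after seeing the data, and it moved no count by more than 1.5 times. For the gene counts of cisplatin with saline, the combination with cisplatin, with dichloroacetate and with saline, 15 of 16 alternatives lay within 1.5 times the count, and for the interaction 20 of 21. The exception was an added absolute log2 fold change of at least 1, which left 3208, 609, 1677, 1614 and 545 genes. Leaving out 1 library gave 11075 to 12029, 4683 to 6488, 6925 to 7508, 6559 to 8056 and 2692 to 4213. For dichloroacetate with saline only 6 of 16 alternatives stayed within 1.5 times 63: DESeq2 called 336 (182 higher, 154 lower, or 54.2% against 41.3% higher), no filter on low counts 119, the 6 libraries alone 15 and the added fold change 1. Leaving out 1 library gave 16 (without dichloroacetate replicate 1) to 126 (without saline replicate 3, 72 higher and 54 lower), with 22 and 21 without saline replicates 1 and 2 and 33 without dichloroacetate replicate 3. The cause was not tested. With the replicate number as a block, 117 genes were called. The numbers were not taken to pair the samples, since over 18 same-numbered pairs the correlations of deviations were -0.095 to 0.152, only 4 above 0.1. As a hint from the data, 6 of 12 samples had their highest correlation with a sample of their own number, and 0 of 12 correlated best with it in every other group. The block moved no other gene or list count by more than 1.5 times.

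With an estimated correlation camera called 1 list for cisplatin with saline, 0 for dichloroacetate with saline, 0 for the combination with cisplatin and 0 for the interaction, and fry called 0 for dichloroacetate with saline. Leaving out 1 library gave 19 to 20, 11 to 15, 16 to 20 and 17 to 20 lists. At least 1 such fit ended the camera call of endoplasmic reticulum stress, cholesterol synthesis and cisplatin uptake for cisplatin with saline, of the clock and macrophage markers for the combination with cisplatin, and of the pyruvate dehydrogenase complex, glutathione genes and macrophage markers for the interaction. For dichloroacetate with saline 10 of the 15 calls ended in at least 1. The downward ones there numbered 2 without saline replicate 3 and 3 without dichloroacetate replicate 2, against 5 with all libraries. The median signed interaction was -0.242 to -0.201 with 1 library left out and passed the threshold without saline replicate 3 (-0.221, exact permutation p = 0.035). It was -0.271 (exact permutation p = 0.005) over genes called for cisplatin with saline, a selection that by construction favours a smaller response with dichloroacetate, and -0.587 (exact permutation p = 0.06) over genes with an average change of at least 1.

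All 1311 values of the 88 genes named for cisplatin with saline and all 75 of the 5 named for the combination with saline kept direction and call. For dichloroacetate with saline 458 of 570 stayed on their side of the threshold, 109 lost and 3 gained the call, and Havcr1 was called under DESeq2, without a filter and without dichloroacetate replicate 3. For the combination with cisplatin, Olfr1442 lost its call under limma-voom, and Lcn2 gained its call without cisplatin replicate 1. For the combination with dichloroacetate 10 of 255 values lost the call, in Pdk1 and Dhrs3. Of 1960 values for 98 genes in the interaction, 57 lost the call, in 10 genes. Cdkn1a was called there without saline replicate 1 or dichloroacetate replicate 3, and Pdk1 without cisplatin replicate 3. The Pdk4 interaction lost its call without dichloroacetate replicate 1, cisplatin replicate 1 or 2 or combination replicate 2. No called value changed sign.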

Other observations

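Of the tests here, those of transcript length or RNA degradation, slopes per mouse and proximal tubule share, and the count of genes with opposite responses, were chosen after the result was seen. Genes called in both cisplatin comparisons with opposite signs numbered 108 of 20370 tested. All were called in the interaction, the difference of the 2 responses, which their selection nearly ensures. Of these 97 were lower with cisplatin alone and higher in the combination against dichloroacetate, and 11 went the other way. Genes named next were chosen after seeing their values. Hao2, a peroxisomal hydroxyacid oxidase, averaged 400.1 CPM in saline, 337 in dichloroacetate, 282 in cisplatin and 646 in the combination, with log2 fold changes of -0.51 (SE 0.10) and 0.94 (SE 0.10). Dhrs3 had -1.08 and 0.23, dopa decarboxylase Ddc -0.61 and 0.59, the methyltransferase Bhmt -0.73 and 1.32, Cyp2d26 -0.33 and 0.62 and Acsl1 -0.41 and 0.49. Dhrs3 lost its 0.23 call without dichloroacetate replicate 1 or 3 or combination replicate 1. Part of this can come from a lower baseline with dichloroacetate alone, which was called for Dhrs3 (-0.41), Cyp2d26 (-0.62) and Acsl1 (-0.54). Dhrs3 lost that call without saline replicate 1 or 2 or dichloroacetate replicate 1 or 3, and Acsl1 without saline replicate 1 or dichloroacetate replicate 2 or 3.

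Long genes fell with cisplatin, and a hypothesis is that their transcripts were completed less often in these mice. Transcript length or RNA degradation is argued against, since the coefficient of log10 genomic span was -0.52 (SE 0.0149, across 19824 genes, which are not independent replicates) with exonic length, GC and mean expression in the fit. Its size depends on that fit, where exonic length had 0.607 (SE 0.025), and span alone had a slope of -0.216. Low expression of long genes is argued against by a coefficient of -0.487 (SE 0.0238) in the top 25% by mean expression. Slopes per mouse with the same terms, relative to saline mice, separated 6 cisplatin-injected mice (-0.56 to -0.274) from 6 others (-0.026 to 0.016). The permutation p of 0.00216, the smallest for 924 arrangements, is not exact, as saline was the reference. The split restates the fall, so it cannot tell slower completion from other causes. The slopes averaged -0.502 in cisplatin and -0.295 in the combination (difference 0.206, exact permutation p = 0.1, the smallest for 3 against 3 mice).

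Male-biased genes had a higher median with dichloroacetate alone, a camera call lost with an estimated correlation. The median of proximal tubule transport genes minus that of male-biased genes was -0.259 (SE 0.0595 from resampling genes, which are not independent replicates). Genes on both lists were counted as male-biased only. This goes against a larger share of proximal tubule RNA as the whole cause, but the SE leaves out the spread among mice. The lower medians of collecting duct (-0.07), podocyte (-0.10) and endothelial (-0.13) markers would go with a larger proximal tubule share. These camera calls were lost with an estimated correlation and without single libraries. The transport genes themselves did not have a higher median, which goes the other way, so a part of that share in the rise stays open. A change in androgen signalling may be involved and was not tested.

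The 10 splits of each pair of groups are too few for a share under 0.05. Every split but the true one mixes the groups compared, putting their difference into the residual spread. So 0 gene calls there set no level for the true count. The true grouping and the highest other split gave 12244 and 0 genes for cisplatin with saline, 63 and 0 for dichloroacetate with saline, 6441 and 0 for the combination with cisplatin, 8286 and 0 for the combination with dichloroacetate and 8189 and 0 for the combination with saline, all with edgeR, and in each case 1 of 10 splits was as large. The same splits gave 20 and 23 lists for cisplatin with saline (3 of 10 as large), 15 and 21 for dichloroacetate with saline (4 of 10) and 18 and 19 for the combination with cisplatin (5 of 10).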
